A study of Papio anubis with 28 samples.

How the data were processed

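Gene expression was measured by RNA sequencing in 28 libraries from the urinary bladder of 14 olive baboons. Each animal gave 1 library of native bladder and 1 library of the tissue grafted into that bladder. In the Entero arm (5 animals) the graft was a segment of ileum, the operation known as enterocystoplasty. In the SIS arm (5 animals) and in the arm labelled PRS (4 animals) the graft was tissue regenerated on a scaffold seeded with primary bone marrow cells, both mesenchymal stromal cells and CD34-positive haematopoietic stem and progenitor cells. SIS is used here for small intestinal submucosa, a sheet of decellularised intestinal matrix. What PRS stands for, the time between surgery and sampling, and the part of each graft that was sampled are not given in the sources used here. Per the labels' protocols, total RNA was extracted from small pieces of tissue, messenger RNA was selected by its poly-A tail, directional libraries were made with dUTP, and paired-end reads were generated on an Illumina platform.

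The values in the table are counts of reads per gene as the authors deposited them, not normalised. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so no coordinates are printed and reads of overlapping or antisense genes cannot be separated. Genes with near-identical copies, such as the defensins, may share reads, and their values are uncertain. The table held 27533 genes, 6280 of them without a symbol, and gene symbols were taken from the table itself. The deposited table also gives a gene length, which was not used in any test. Totals ran from 20975648 to 35669026 counts per library.

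Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its minimum count of 10, which left 17177 genes, 15120 with a symbol. Libraries were scaled by TMM (trimmed mean of M values). All 28 libraries entered 1 quasi-likelihood model with the 6 groups as its terms, so that the groups shared the estimate of spread, and contrasts gave the graft against the native bladder in each arm, the difference of that change between arms, graft against graft, and native against native. P-values were adjusted over all genes tested by Benjamini and Hochberg's method, with a threshold of 0.05. For genes with 1 to 3 reads in a group, the ratio of unscaled CPM has an exact interval of the counts. Log2 fold changes are printed with a standard error (SE). It was taken back from the test, as the absolute log2 fold change over the square root of the F value. The intervals of fold changes rest on it. With few reads in a group it is approximate, and SEs of separate contrasts need not combine to that of their difference. Levels are printed as CPM (read counts scaled to a common library total) on TMM-scaled library sizes, as mean ± SD. Where a group had no read of a gene, the fold is a lower bound, computed from unscaled totals with 3 counts over the whole group in place of 0. Intervals are at 95%. Those of fold changes take in the spread between animals, while those of read ratios and the floors cover counting error only.

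For this purpose 29 gene lists were written before the data were examined, together with the tests, the sample groups and the rule for the genes named. The rule took, from each graft-against-native comparison, the 6 genes with the largest rise and the 6 with the largest fall among genes with a symbol that passed the threshold and moved the same way in every animal. In the other comparisons it took the 4 largest in each direction that passed. It added from every list up to 4 tested members with the smallest p, whether or not they passed, and a fixed set of marker genes (among them UPK1A, UPK2, UPK3A, CDX2, VIL1, ACTG2, DES, COL1A1, PECAM1, CD3E and CD34). A gene named for 1 comparison may be followed in others, and genes of the rule were left out for room. Lists were tested with camera in limma 3.58.1, which compares a list with all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists of a comparison. The same test with a correlation estimated from the data is printed beside each call it ends. Counts of list members are given over all genes tested, and adjusted over the list alone.

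The distance of a graft from the native bladder of its animal was 1 minus Pearson's r between the log2(CPM + 1) values of the libraries, over the genes that passed the filter. Arms were compared by a two-sided exact permutation test of the difference in means. The mitochondrial share was tested in the same way between groups and, with the pairs kept, by exact sign flips. Native and graft libraries came from the same animals, per the codes in the labels, and a fit with the animal as a block was 1 of the alternatives fixed in advance. The deviations from the group means of an animal's native and graft libraries correlated with r from -0.19 to 0.61. The highest r of a native library with another animal's graft of its arm ran from 0.04 to 0.4. This highest r lay above the own r in most Entero and SIS animals, so the pairing is not plain there. An own r set against the highest of several others would seldom exceed it by chance. In the PRS arm the own r was higher in animals 2 (0.29 against 0.09), 3 (0.17 against 0.09) and 4 (0.61 against 0.34). It was lower in animal 1 (0.18 against 0.4). The lowest chi-square per degree of freedom between 2 libraries of a group was 72.2, so no library was counted as a repeat of another. The letter F or M of the animal code was used only as a covariate of that name.

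The alternatives fixed in advance were DESeq2 1.42.0, the median-of-ratios size factors, a fit of the compared groups alone, no filter and a stricter filter (mean CPM of at least 1), the block, the letter of the animal code, and leaving out each library in turn. For distances they were Spearman's rho, the 500 most variable genes, a pseudocount of 0.1 and the stricter filter. Fits without mitochondrial genes, fits of the cell-seeded arms alone and fits with the smooth muscle score as a covariate were added after the data were seen. The pipeline was tested on a single draw of simulated counts per comparison, with known changes. Genes were drawn independently, with edgeR's estimates of spread and the same mean in all groups before the changes. For the ileum, SIS and PRS comparisons below, 196, 197 and 196 of the genes tested were changed. With so few changed genes the adjusted threshold is stricter than among the many calls of the real Entero comparison, so that recovery does not carry over to it. In the comparison of ileum with native bladder, 51.5% of genes changed 4-fold and 3.09% of genes changed 2-fold were recovered (16785 genes tested). For the SIS arm the recovery was 45.5% and 6.12% (16837 genes), and for the PRS arm 27.8% and 5.05% (16803 genes). In those tests edgeR made 0, 3 and 0 false calls, and DESeq2 made 14 of 81, 29 of 98 and 31 of 103.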

Results

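The 28 libraries fall into 6 groups: native bladder and ileum graft in the Entero arm (5 animals), native bladder and regenerated tissue in the SIS arm (5 animals), and native bladder and regenerated tissue in the PRS arm (4 animals). Total counts per library lay between 20975648 and 35669026. At this depth a gene without a read in the 5 ileum libraries lies below 0.0237 CPM over the group. Transcripts of muscle differed widely between animals within a group. DES, the intermediate filament of muscle cells, ranged from 2840 to 32700 CPM over the 5 native libraries of the Entero arm and from 1140 to 28800 CPM over the 4 of the PRS arm.

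The comparison of ileum graft with native bladder asked how far bowel placed in the bladder wall differed from the wall itself. The series holds no ungrafted ileum, so traits of bowel cannot be told apart from changes after grafting. Here rose and fell mean higher and lower in the graft than in native bladder. The ileum grafts carried the transcripts of intestinal epithelium at high levels and those of urothelium, the lining of the bladder, at low levels. Transcripts of the smooth muscle contractile apparatus showed no difference that passed the test. In edgeR's quasi-likelihood test 1328 genes rose and 1254 fell in the graft, 2582 in all, and 2221 of these changed at least 2-fold.

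All 28 tested genes of the absorptive intestinal epithelium rose (adjusted p = 3.11e-39 for the list by camera, adjusted p = 0.000477 with an estimated correlation). VIL1 (ENSPANG00000005751), which bundles actin in microvilli, stood at 711 ± 461 CPM in ileum and at 0.487 ± 0.186 CPM in native bladder (n = 5 each), a log2 fold change of 10.50 (SE 0.89, adjusted p = 1.79e-08). CDX2 (ENSPANG00000024013), the transcription factor that maintains intestinal identity, rose from 0.209 ± 0.187 to 139 ± 38.3 CPM (log2 fold change 9.32, SE 1.04). FABP2, a fatty acid-binding protein of enterocytes, rose by a log2 fold change of 10.30 (SE 0.91). SLC6A19, a neutral amino acid transporter of the brush border, rose by 9.25 (SE 1.06), and RBP2, which carries retinol in enterocytes, by 10.59 (SE 1.24). Among the genes with the largest rises were SLC5A12, a lactate transporter (12.22, SE 1.12), and SMIM24 (11.37, SE 0.83). SLC17A4, SST and NAT16 had no read in the 5 native libraries and were at least 924-fold, 667-fold and 464-fold higher in ileum, against a floor of 3 counts over the group.

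Of 17 secretory and crypt genes, 10 rose, 1 fell and 6 did not pass (12 rose and 1 fell adjusted over the list alone). The list ranked above other genes (adjusted p = 3.06e-05 by camera), and this call ended at adjusted p = 0.286 with an estimated correlation. ZG16, a goblet cell lectin, stood at 1870 ± 1740 CPM in ileum and 1.85 ± 1.42 CPM in native bladder (log2 fold change 9.97, SE 1.56, adjusted p = 0.000127). TFF3, a goblet cell peptide, rose by 9.56 (SE 2.01), DEFA6, a Paneth cell defensin, by 11.13 (SE 1.46), and ATOH1, the transcription factor of the secretory lineage, by 9.34 (SE 1.5).

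Of 14 urothelial genes, 11 fell, 0 rose and 3 did not pass (12 fell adjusted over the list alone, and 12 fell in DESeq2). The list ranked below other genes (adjusted p = 3.52e-14 by camera), with adjusted p = 0.146 with an estimated correlation. The uroplakins, which form the plaques on the urine-facing membrane, fell together. UPK1A (ENSPANG00000018900) stood at 3.03 ± 2.74 CPM in ileum and 936 ± 804 CPM in native bladder (log2 fold change -8.27, SE 1.37, adjusted p = 0.000133). UPK2 (ENSPANG00000018904) changed by -8.58 (SE 1.5, adjusted p = 0.000236) and UPK3A (ENSPANG00000023977) by -7.63 (SE 1.15, adjusted p = 4.95e-05). TP63 (ENSPANG00000006656), the transcription factor of basal epithelial cells, changed by -10.12 (SE 1.35). It had 3 reads over the 5 ileum libraries and 5266 over the 5 native ones, a ratio of 1750 with a counting interval of 597 to 8470. SNX31, which is found with uroplakins in umbrella cells, changed by -8.74 (SE 1.18), and GRHL3, a transcription factor of barrier epithelia, by -4.80 (SE 0.76). TMEM40 changed by -11.65 (SE 1.21), with 1 read in ileum against 6332 (ratio 6300, counting interval 1130 to 249000). CLC, the Charcot-Leyden crystal galectin, changed by -11.58 (SE 2.46).

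Squamous differentiation genes went both ways: of 8 tested, 4 fell and 1 rose (adjusted p = 0.0164 for the list, adjusted p = 0.55 with an estimated correlation; 5 fell and 1 rose adjusted over the list alone). KRT6A, a keratin of stratified epithelium, changed by -7.72 (SE 1.33) and DSG3, a desmosomal cadherin, by -6.92 (SE 1.28), whereas the transglutaminase TGM3 rose by 5.97 (SE 1.54, adjusted p = 0.00972). The squamous list mean was -0.34 in native library 4, within the -2.62 to 0.95 of the ileum grafts, and 2.57 to 3.65 in the other native libraries. Graft minus native gave -5.19 to -0.80 over the 5 animals. Of 20 WNT and hedgehog genes, 2 fell, both epithelial ligands. WNT7B changed by -9.15 (SE 1.18, adjusted p = 8.1e-06) and SHH by -8.88 (SE 1.23, adjusted p = 1.65e-05). That list passed with adjusted p = 0.0343, with adjusted p = 0.55 with an estimated correlation and 0.0577 with the animal as a block.

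Among the largest falls were 3 transcription factors, HOXD13, TBX4 and TBX5, which had no read in the 5 ileum libraries and were at least 1340-fold, 1030-fold and 657-fold higher in native bladder, against the same floor. TMPRSS11E, a serine protease of stratified epithelium, was at least 1420-fold higher.

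Smooth muscle genes gave 0 calls of 16 in edgeR, 1 at unadjusted p under 0.05 and 0 in DESeq2 (adjusted p = 0.98 for the list). DES (ENSPANG00000017460) stood at 15600 ± 15400 CPM in ileum and 9980 ± 12700 CPM in native bladder, a log2 fold change of 0.65 with an interval of -1.37 to 2.66. ACTG2, the gamma actin of visceral muscle, gave 0.99 with an interval of -1.23 to 3.20. Of 16 receptors and channels of bladder contraction, 3 fell and 0 rose, and the list did not pass (adjusted p = 0.237). TRPV4, a stretch- and osmosensitive cation channel also found in urothelium, changed by -4.42 (SE 0.92, adjusted p = 0.0015), and EDNRA, an endothelin receptor, by -1.66 (SE 0.48, adjusted p = 0.0177). Of 17 neuronal genes 2 rose, and the list did not pass (adjusted p = 0.152). TAC1, the precursor of substance P, rose by 4.81 (SE 1.22, adjusted p = 0.00762).

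In the matrix, 5 of 15 elastic fibre and basement membrane genes fell (6 adjusted over the list alone; adjusted p = 0.0196 for the list, adjusted p = 0.843 with an estimated correlation). MFAP5, a microfibril protein, changed by -3.84 (SE 0.93) and LTBP4, which takes part in elastic fibre assembly, by -1.74 (SE 0.45). The list mean was 7.19 in ileum library 3 and 6.11 to 6.38 in the other ileum libraries, against 6.86 to 8.85 in native bladder. It was higher in the graft in 1 of 5 animals. Of 25 genes of fibrillar collagen and fibrosis, 2 rose and 1 fell (adjusted p = 0.332 for the list). TNC, tenascin C, rose by 3.38 (SE 0.77, adjusted p = 0.00346), and COL1A1 gave -0.93 (SE 0.77, adjusted p = 0.47).

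Immune genes gave calls in some lists and none in others. Of 15 interferon response genes, 5 fell and 0 rose, and 9 fell and 1 rose adjusted over the list alone (adjusted p = 0.00644 for the list, adjusted p = 0.705 with an estimated correlation). The interferon list mean was 6.02 in native library 2 and 3.73 to 4.37 in the other 4 native libraries, and graft minus native gave -1.99 to -0.20 over the 5 animals. IFI44L changed by -2.70 (SE 0.42, adjusted p = 5.76e-05). Of 14 cytokines and chemokines, 2 fell (adjusted p = 0.332 for the list): IL33, an alarmin of barrier tissue, by a log2 fold change of -3.83 (SE 0.53), and IL1A by -4.81 (SE 1.23). S100A9, a neutrophil and squamous epithelial protein, changed by -6.30 (SE 1.28), the 1 call among 8 neutrophil and mast cell genes. CD68, a lysosomal protein of macrophages, rose by 1.82 (SE 0.44), the 1 call among 15 macrophage genes. T and natural killer cell genes gave 0 calls of 16 in edgeR, 1 at unadjusted p under 0.05 and 1 in DESeq2, and CD3E gave -0.13 (SE 0.78). B and plasma cell genes gave 0 calls of 15 in edgeR, 3 at unadjusted p under 0.05 and 2 in DESeq2, and JCHAIN, which joins secreted immunoglobulins, gave 2.81 (SE 1.25, adjusted p = 0.134).

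Cell division genes rose in part, 6 of 17 over all genes tested and 11 adjusted over the list alone (adjusted p = 3.78e-07 for the list, adjusted p = 0.55 with an estimated correlation). PCNA, the replication clamp, rose by 1.13 (SE 0.32, adjusted p = 0.0174). That call was lost without native library 1 (adjusted p = 0.0502), native library 5 (0.0515), ileum library 4 (0.0754) or ileum library 5 (0.0661), and in a fit of the 2 groups alone (0.0981). Of 12 hypoxia and glycolysis genes, 3 rose and 2 fell (adjusted p = 0.332 for the list). CA9, a carbonic anhydrase also made by gut epithelium, rose by 4.01 (SE 0.76), LDHA, lactate dehydrogenase, rose by 1.75 (SE 0.41), and SLC2A1, the glucose transporter, changed by -2.16 (SE 0.50). Of 12 genes of haematopoietic stem and progenitor cells, 1 rose and 2 fell (adjusted p = 0.711 for the list). GATA2 changed by -4.46 (SE 0.70, adjusted p = 6.79e-05). CD34, also a marker of vessels and stroma, changed by -1.75 (SE 0.46, adjusted p = 0.0103), and by -1.27 without native library 4 (adjusted p = 0.0531). Endothelial genes gave 2 falls of 13, and PECAM1 gave 0.11 (SE 0.39). Of 12 mesenchymal stromal genes 3 fell (adjusted p = 0.101 for the list).

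Transcripts of the 13 mitochondrial genes took 19.8 ± 8.0% of counts in ileum grafts and 8.4 ± 1.4% in the native bladders of that arm (n = 5 each; two-sided exact permutation p = 0.00794, the smallest this test allows). The share was higher in the graft in 5 of 5 animals. A test that keeps the pairs, by exact sign flips, gave a two-sided p of 0.0625, the smallest that 32 flips allow, so it could not pass 0.05. Of the 13 genes 9 rose and 0 fell in edgeR. The means of the other 4 groups lay between 8.2% and 9.7%. Ileum library 1 stood apart at 33.9%, against 14.0% to 18.5% in the other ileum libraries.

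**Figure D1:**
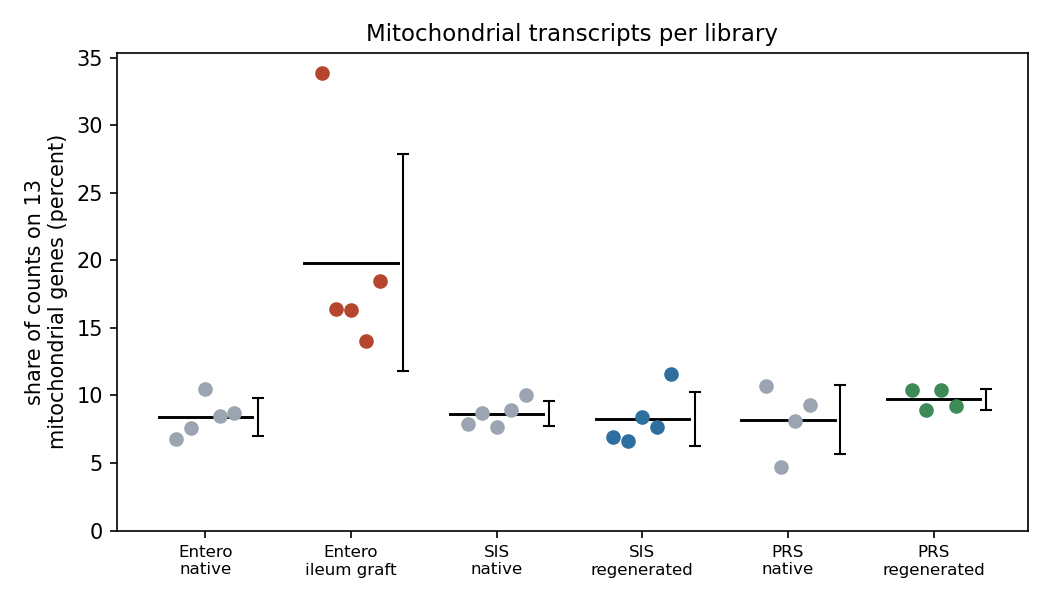
Share of counts on the 13 mitochondrial genes in each library (percent, vertical axis) for the 6 groups (horizontal axis). Points are libraries, horizontal lines the group means and bars ± 1 SD; ileum grafts lie between 14.0% and 33.9%, above the 6.8% to 10.5% of their native bladders.

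The comparison of SIS regenerated tissue with native bladder asked how far tissue grown on a cell-seeded scaffold differed from the bladder it joined. Uroplakin, collagen and vessel transcripts were present in regenerated tissue, with intervals of the fold change that spanned 0. UPK1A stood at 1020 ± 758 CPM in regenerated tissue and 1070 ± 841 CPM in native bladder (n = 5 each), a log2 fold change of -0.07 with an interval of -2.12 to 1.98. UPK2 gave -0.12 (interval -2.33 to 2.08) and UPK3A 0.41 (interval -1.37 to 2.18). COL1A1 gave 0.19 (interval -1.39 to 1.76), PECAM1 -0.20 (interval -0.99 to 0.59), CD34 -0.69 (interval -1.62 to 0.24) and CD3E 0.69 (interval -0.91 to 2.30). Of the intestinal markers, VIL1 stood at 0.107 ± 0.104 and 0.0645 ± 0.0924 CPM (log2 fold change 0.77, interval -1.21 to 2.74). CDX2 had no read in native bladder and 12 reads in regenerated tissue, all in library 2, at least 3.99-fold higher over the group. SLC5A1, the sodium-glucose transporter, gave 5.53 (interval 1.05 to 10.01, adjusted p = 0.914), and 0.82 without regenerated library 4, which held 36.7 CPM.

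In edgeR 0 of 17177 genes passed, 831 had an unadjusted p under 0.05, and DESeq2 called 63 higher and 7 lower. For 64.7% of genes the 95% interval of the fold change lay within 4-fold in either direction. Lists moved as groups only with the preset correlation. Immediate early response genes, which respond to tissue handling among other stimuli, ranked higher in regenerated tissue (adjusted p = 1.58e-07 by camera, adjusted p = 0.441 with an estimated correlation), as did T and natural killer cell genes (adjusted p = 5.3e-06, adjusted p = 0.49 with an estimated correlation). Smooth muscle genes ranked lower (median log2 fold change -1.28, adjusted p = 1.09e-05, adjusted p = 0.563 with an estimated correlation), and DES gave -0.95 (interval -2.98 to 1.07) and ACTG2 -1.34 (interval -3.57 to 0.90). The smooth muscle list mean was higher in the graft in 2 of 5 animals, with differences of -3.78 to 1.91. Elastic fibre and basement membrane genes ranked lower (adjusted p = 0.000692, adjusted p = 0.599 with an estimated correlation), as did neuronal genes (adjusted p = 0.0045, adjusted p = 0.49 with an estimated correlation). The neuronal list mean was 3.31 in native library 4 and -0.29 to 0.10 in the other 4 native libraries. Urothelial genes did not pass (adjusted p = 0.0562), and ranked higher with the animal as a block (adjusted p = 0.0173), against adjusted p = 0.84 with an estimated correlation and no block. Secretory and crypt genes (adjusted p = 0.0149) and squamous genes (adjusted p = 0.018) ranked higher as well, each with adjusted p = 0.49 with an estimated correlation. Both list means were higher in the graft in 3 of 5 animals. Haematopoietic stem and progenitor genes ranked higher with adjusted p = 0.035, and adjusted p = 0.457 with an estimated correlation. Over all genes tested, edgeR called 0 members of these lists. Unadjusted p lay under 0.05 for 5 immediate early, 2 T and natural killer cell, 0 smooth muscle, 0 elastic fibre, 6 neuronal and 1 urothelial genes, of which DESeq2 called 1, 0, 0, 0, 1 and 0. It also lay under 0.05 for FCGBP and CLCA1 among secretory genes and for KRT16 and KRT4 among squamous genes. The same held for RUNX1, PROM1, MYB and KIT among haematopoietic genes. KIT is also on the list of interstitial cells, and CD34, a member of the haematopoietic list, gave -0.69. The haematopoietic list mean was higher in the graft in 3 of 5 animals, with differences of -0.24 to 1.6.

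Cytokine and chemokine genes ranked higher in SIS regenerated tissue (adjusted p = 1.89e-05, adjusted p = 0.441 with an estimated correlation). Of 14 members 0 passed over all genes tested in edgeR, 4 had an unadjusted p under 0.05, 2 were called by DESeq2, and 4 were higher adjusted over the list alone. The list mean was higher in the graft in 5 of 5 animals, by 1.66 ± 1.0 log2 units and at least 0.18. In the same 5 animals the immediate early list mean was also higher, by 1.32 ± 0.91 (0.40 to 2.39). Whether these rises share a source was not tested. The size of the change in single members of the cytokine list depended on regenerated library 2. IL6, a cytokine of acute inflammation, was at 599 CPM there and between 0.408 and 5.49 CPM in the other 4 regenerated libraries. Its log2 fold change was 7.51 (SE 1.68, adjusted p = 0.341) with that library and 2.19 without it. PTGS2, the inducible cyclooxygenase, gave 4.47 with it and 1.61 without, CXCL8, which attracts neutrophils, 6.64 and 3.52, and CCL2, which attracts monocytes, 4.63 and 0.31. Mesothelial genes ranked higher too (adjusted p = 0.0149, adjusted p = 0.441 with an estimated correlation). Their list mean was higher in the graft in 5 of 5 animals, by 0.31 to 4.08. Among them MSLN gave 6.0 (SE 1.94, adjusted p = 0.693) with regenerated library 4 and 1.62 without it. FCGBP, a mucus protein, was at 4980 CPM in library 4 and gave 6.32 with it and 2.00 without.

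The comparison of PRS regenerated tissue with native bladder asked the same of the second scaffold. Uroplakin transcripts were present in all 4 regenerated libraries, with means below those of native bladder and intervals that reached 0. UPK1A stood at 304 ± 355 CPM in regenerated tissue and 1120 ± 952 CPM in native bladder (n = 4 each), a log2 fold change of -1.88 with an interval of -4.25 to 0.48. UPK2 gave -1.66 (interval -4.19 to 0.87) and UPK3A -0.11 (interval -2.09 to 1.88). DES gave -0.47 (interval -2.72 to 1.78), ACTG2 -0.34 (interval -2.79 to 2.12), COL1A1 0.73 (interval -1.04 to 2.51) and CD34 0.27 (interval -0.77 to 1.3).

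In edgeR 0 of 17177 genes passed, 613 had an unadjusted p under 0.05, and DESeq2 called 22 higher and 4 lower. Without native library 4, edgeR called 3 genes higher, RAB44, TRPC4 and P2RX7, which were chosen after their values were seen. For 62.3% of genes the interval lay within 4-fold in either direction. Urothelial genes ranked lower in regenerated tissue (adjusted p = 0.000204 by camera, adjusted p = 0.735 with an estimated correlation). Endothelial genes ranked higher (adjusted p = 0.00147, adjusted p = 0.735 with an estimated correlation), and KDR, a receptor for vascular endothelial growth factor, gave 1.45 (SE 0.59) and PECAM1 1.06 (SE 0.44), both with an adjusted p of 1. Immediate early genes ranked higher (adjusted p = 5e-04, adjusted p = 0.735 with an estimated correlation; 2 higher adjusted over the list alone), and FOS gave 2.82 (SE 0.86) and DUSP1, a phosphatase induced by stress, 2.60 (SE 0.78). Macrophage genes ranked lower (adjusted p = 0.00278, adjusted p = 0.766 with an estimated correlation), with C1QC, a complement component made by macrophages, at -1 (SE 0.48). Their list mean was higher in the graft in 1 of 4 animals. T and natural killer cell genes ranked lower (adjusted p = 0.00625, adjusted p = 0.766 with an estimated correlation). That list mean was higher in the graft in 2 of 4 animals, with differences of -1.34 to 1.08. WNT and hedgehog genes ranked lower (adjusted p = 0.0138, adjusted p = 0.735 with an estimated correlation) and angiogenic and growth factor genes higher (adjusted p = 0.0165, adjusted p = 0.735 with an estimated correlation). VIL1 gave 4.23 (SE 1.12, adjusted p = 1) at low levels, 43 reads over the 4 regenerated libraries and 2 over the 4 native ones (ratio 22.8, counting interval 5.93 to 194). Over all genes tested, edgeR called 0 members of these lists. Unadjusted p lay under 0.05 for 1 urothelial, 2 endothelial, 5 immediate early, 1 macrophage, 1 T and natural killer cell, 0 WNT and hedgehog and 2 growth factor genes, and DESeq2 called 0 of each. With the animal as a block, smooth muscle genes ranked lower (adjusted p = 0.0149, 0.149 without it) and secretory and crypt genes (adjusted p = 0.0148, 0.0563 without it), mesothelial genes (adjusted p = 0.0358, 0.0767 without it) and adipocyte genes (adjusted p = 0.0358, 0.0918 without it) ranked higher. With an estimated correlation and no block these lists gave adjusted p of 0.827, 0.766, 0.735 and 0.827. The smooth muscle list mean was higher in the graft in 1 of 4 animals, the secretory and crypt mean in 3 of 4 and the adipocyte mean in 2 of 4. The adipocyte mean was 5.17 in native library 4 and 1.54 to 2.13 in the other native libraries. The mesothelial list mean was higher in the graft in 4 of 4 animals, by 0.35 to 2.66. Its members did not all rise: LRRN4 gave 9.13 (SE 2.79), ITLN1 4.66 (SE 2.34) and MSLN 3.36 (SE 1.9), while UPK3B gave -1.21 (SE 0.87). With an estimated correlation 0 of the 29 lists passed in this arm, the lowest at 0.735.

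Whether the change from native bladder to graft differed between arms was tested as the difference of the changes. The change in urothelial genes was higher, and the change in absorptive intestinal genes lower, in the SIS arm than in the Entero arm. Of the 29 lists 10 were called, and 2 with an estimated correlation. In edgeR the change was higher in the SIS arm for 611 genes and lower for 507, 1118 in all. With the animal as a block 678 genes passed, 354 higher and 324 lower, and 624 were called in both fits. Of 14 urothelial genes 11 were higher, 14 adjusted over the list alone (adjusted p = 2.91e-19, adjusted p = 0.0317 with an estimated correlation). The differences of log2 fold change were 8.20 for UPK1A (SE 1.60, adjusted p = 0.0019), 8.45 for UPK2 (SE 1.74), 8.04 for UPK3A (SE 1.38) and 10.60 for TP63 (SE 1.57). WNT7B differed by 9.68 (SE 1.38), SHH by 9.98 (SE 1.46), IL33 by 4.17 (SE 0.70), GATA2 by 4.21 (SE 0.89) and TRPV4 by 5.19 (SE 1.19). Of 28 absorptive genes 16 were lower, 18 adjusted over the list alone (adjusted p = 3.5e-18, adjusted p = 0.0126 with an estimated correlation), among them SLC6A19 at -11.20 (SE 1.51) and VIL1 at -9.73 (SE 1.5). CA9 differed by -4.38 (SE 1.0). Of 17 neuronal genes 4 were lower, 8 adjusted over the list alone (adjusted p = 0.00698, adjusted p = 0.543 with an estimated correlation), in a test that includes SIS native library 4 with its list mean of 3.31.

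Of 14 cytokines and chemokines 5 differed, all higher in the SIS arm (adjusted p = 0.00224, adjusted p = 0.498 with an estimated correlation). CXCL8 differed by 8.19 (SE 2.00, adjusted p = 0.0115), and by 5.08 without SIS regenerated library 2 (adjusted p = 0.0613). PTGS2 differed by 5.18 (SE 1.34, adjusted p = 0.0172), by 2.32 without that library (adjusted p = 0.141) and by 3.37 with the animal as a block (adjusted p = 0.144). No difference passed for DES (-1.60, interval -4.46 to 1.26), ACTG2 (-2.33, interval -5.47 to 0.82), COL1A1 (1.12, interval -1.12 to 3.35) or CD34 (1.06, interval -0.25 to 2.38).

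The PRS arm too differed from the Entero arm in urothelial and absorptive genes. Of the 29 lists 8 were called, and 0 with an estimated correlation. Cytokines (adjusted p = 0.385) and neuronal genes (adjusted p = 0.468) did not pass. In edgeR the change was higher in the PRS arm for 274 genes and lower for 332, 606 in all. With the animal as a block 240 passed (98 higher, 142 lower), 218 of them called in both fits, 371 passed in a fit of the 4 groups alone, and 390 without PRS regenerated library 1. Of 14 urothelial genes 8 were higher, 11 adjusted over the list alone (adjusted p = 4.83e-12, adjusted p = 0.218 with an estimated correlation). UPK3A differed by 7.52 (SE 1.46, adjusted p = 0.00336, 0.0506 with the block) and TP63 by 8.49 (SE 1.62, adjusted p = 0.00326). UPK1A differed by 6.39 (SE 1.64, adjusted p = 0.0263), a call lost with the block (adjusted p = 0.0628) and without Entero native library 3 (0.0541), PRS native library 1 (0.0606), PRS native library 4 (0.0611) or PRS regenerated library 1 (0.0848). WNT7B differed by 8.56 (SE 1.44), SHH by 8.53 (SE 1.51), IL33 by 4.24 (SE 0.74) and LEPR, the leptin receptor of stromal cells, by 4.01 (SE 0.89). Of 28 absorptive genes 13 were lower, 16 adjusted over the list alone (adjusted p = 2.31e-12, adjusted p = 0.0848 with an estimated correlation), among them the peptidase ANPEP at -8.69 (SE 1.29) and MTTP, which loads lipid onto lipoproteins, at -9.01 (SE 1.60). VIL1 gave -6.27 (SE 2.45, adjusted p = 0.179), DES -1.12 (SE 1.47), COL1A1 1.67 (SE 1.16) and CD34 2.02 (SE 0.68, adjusted p = 0.105).

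Between the PRS and SIS arms 0 genes differed in edgeR, 677 had an unadjusted p under 0.05, and DESeq2 called 20. Of the 29 lists 6 were called, and 0 with an estimated correlation. Urothelial genes ranked lower in the PRS arm (adjusted p = 1.74e-05), as did T and natural killer cell genes (adjusted p = 1.94e-07), cytokines (adjusted p = 0.000124), squamous genes (adjusted p = 0.0079) and WNT and hedgehog genes (adjusted p = 0.0148), each with adjusted p = 0.393 with an estimated correlation. Neuronal genes ranked higher (adjusted p = 0.0135, adjusted p = 0.582 with an estimated correlation), in a test that includes SIS native library 4 (list mean 3.31, others -0.29 to 0.10) and PRS regenerated library 1 (0.19, others -0.88 to -0.76). The cytokine list mean was 0.44 in PRS regenerated library 2 and 2.66 to 2.98 in the other 3. UPK1A differed by -1.81 (interval -4.91 to 1.28), UPK2 by -1.53 (interval -4.86 to 1.79) and UPK3A by -0.51 (interval -3.18 to 2.15). IL6 gave -6.54 (SE 2.10, adjusted p = 1), CXCL8 -5.26 (SE 1.99), CCL2 -4.39 (SE 1.64) and PTGS2 -2.82 (SE 1.36), values that include SIS regenerated library 2. DES gave 0.48, COL1A1 0.55, CD34 0.96 and PECAM1 1.26, each with an adjusted p of 1.

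Set directly against ileum grafts, urothelial, collagen and immediate early genes ranked higher in SIS regenerated tissue, and intestinal, B cell and cell division genes lower. Of the 29 lists 11 were called, and 1 with an estimated correlation, the absorptive genes. In edgeR 1875 genes were higher and 1752 lower, 3627 in all, and 2314 passed in a fit of the 2 groups alone. The animals differ between the arms, and their native bladders differed the same way in several of these lists. Absorptive genes (adjusted p = 2.17e-36, adjusted p = 0.000172 with an estimated correlation), secretory and crypt genes (adjusted p = 0.036, adjusted p = 0.399 with an estimated correlation), B and plasma cell genes (adjusted p = 7.06e-19, adjusted p = 0.13 with an estimated correlation) and cell division genes (adjusted p = 1.56e-08, adjusted p = 0.33 with an estimated correlation) ranked lower in SIS than in Entero native bladder. Immediate early genes (adjusted p = 9.35e-05, adjusted p = 0.33 with an estimated correlation) and collagen genes (adjusted p = 5.88e-09, adjusted p = 0.33 with an estimated correlation) ranked higher there. All 14 urothelial genes were higher (adjusted p = 2.24e-14, adjusted p = 0.138 with an estimated correlation), with UPK1A at 8.40 (SE 1.38), UPK2 at 8.49 (SE 1.49) and UPK3A at 7.88 (SE 1.17), and all 28 absorptive genes were lower (adjusted p = 1.01e-44, adjusted p = 0.000217 with an estimated correlation), with VIL1 at -12.69 (SE 0.98). Of 25 collagen and fibrosis genes 12 were higher, 16 adjusted over the list alone (adjusted p = 0.000464, adjusted p = 0.628 with an estimated correlation). The collagen list mean was 9.22 in SIS regenerated library 2 and 6.33 to 6.91 in the other 4. COL3A1 stood at 1490 ± 1240 CPM in SIS tissue and 274 ± 229 CPM in ileum (log2 difference 2.45, SE 0.63, adjusted p = 0.00654). Of 15 B and plasma cell genes 14 were lower (adjusted p = 1.38e-05, adjusted p = 0.483 with an estimated correlation), and CD79A, part of the B cell receptor, stood at 2.08 ± 0.882 against 74.8 ± 98.4 CPM. Of 17 cell division genes 16 were lower (adjusted p = 1.03e-11, adjusted p = 0.325 with an estimated correlation), with CCNB1, the mitotic cyclin, at -3.58 (SE 0.76). Of 13 immediate early genes 7 were higher (adjusted p = 0.000464, adjusted p = 0.52 with an estimated correlation), with FOSB at 5.26 (SE 1.22). CD34 was higher by 1.58 (SE 0.46), GATA2 by 4.31 (SE 0.69) and IL33 by 3.98 (SE 0.54), while DES (-1, SE 0.98) and ACTG2 (-1.36, SE 1.09) did not pass.

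Against ileum grafts, PRS regenerated tissue was higher in 1239 genes and lower in 1153, 2392 in all, and 1033 passed in a fit of the 2 groups alone. Of the 29 lists 11 were called, and 1 with an estimated correlation, the absorptive genes. Of 14 urothelial genes 13 were higher (adjusted p = 1.36e-12, adjusted p = 0.206 with an estimated correlation), with UPK1A at 6.65 (SE 1.29), UPK2 at 6.79 (SE 1.41) and UPK3A at 7.64 (SE 1.17). Of 28 absorptive genes 27 were lower (adjusted p = 5.05e-46, adjusted p = 8.63e-05 with an estimated correlation), with VIL1 at -10.80 (SE 1.0). Absorptive genes ranked lower in PRS than in Entero native bladder as well (adjusted p = 4.18e-35, adjusted p = 0.000158 with an estimated correlation). In the difference of change, which takes the native bladders as reference, 13 of the 28 genes were still lower, while VIL1 did not pass (-6.27, adjusted p = 0.179). That value for VIL1 rests on few reads, 43 over the PRS regenerated libraries and 2 over the PRS native ones. The intestinal signal in Entero native libraries was small, 0.023% to 0.184% of the ileum mean over 20 marker genes. Of 17 cell division genes 8 were lower, 16 adjusted over the list alone (adjusted p = 2.98e-08, adjusted p = 0.538 with an estimated correlation), with CCNB1 at -3.39 (SE 0.83). HOXD13, without a read in ileum, was at least 833-fold higher in PRS tissue. TRPV4 was higher by 4.46 (SE 0.94), LEPR by 3.65 (SE 0.65) and IFI44L by 2.14 (SE 0.42). CD34 was higher by 1.96 (SE 0.48, adjusted p = 0.0071), and by 1.35 without PRS regenerated library 2 (adjusted p = 0.0659). BPIFB1, a secreted protein of mucosal glands, was higher by 12.20 (SE 2.96, adjusted p = 0.00638), with 0 to 3840 CPM over the 4 PRS libraries. That call was lost with the letter of the animal code as a covariate (adjusted p = 0.253). COL1A1 (1.59, SE 0.82) and DES (-0.53, SE 1.04) did not pass.

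Between PRS and SIS regenerated tissue 0 genes passed in edgeR, 763 had an unadjusted p under 0.05, and DESeq2 called 15. Of the 29 lists 7 were called, and 0 with an estimated correlation. B and plasma cell genes ranked higher in PRS tissue (adjusted p = 1.05e-09, adjusted p = 0.363 with an estimated correlation). Cell division genes did too (adjusted p = 2.75e-05, adjusted p = 0.813 with an estimated correlation). The B cell list mean ran from -0.54 to 5.22 over PRS and from 0.01 to 1.12 over SIS regenerated libraries. The cell division mean ran from 1.3 to 3.75 and from 1.44 to 2.37. In both lists the lowest PRS library lay below every SIS library. Squamous genes (adjusted p = 7.22e-05), WNT and hedgehog genes (adjusted p = 0.0011) and hypoxia genes (adjusted p = 0.0228) ranked lower, each with adjusted p = 0.259 with an estimated correlation. Collagen genes ranked lower too (adjusted p = 2.91e-05, adjusted p = 0.813 with an estimated correlation), against SIS tissue that includes library 2 with its collagen list mean of 9.22. Urothelial genes ranked lower (adjusted p = 2.91e-05, adjusted p = 0.575 with an estimated correlation), with UPK1A at -1.75 (SE 1.11), UPK2 at -1.70 (SE 1.19) and UPK3A at -0.24 (SE 0.92). TFF3 gave 8.60 (SE 2.07), FCGBP 4.10 (SE 1.91), IL6 -4.94 (SE 1.63), COL1A1 -0.69 (SE 0.82), CD34 0.39 (SE 0.48) and DES 0.47 (SE 1.03), each with an adjusted p of 1. Without SIS regenerated library 2, IL6 gave 0.37.

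The native bladders of the 3 arms serve as the reference of each graft and were compared with each other. Uroplakin transcripts were at like mean levels, while the native bladders of the Entero arm held low levels of absorptive intestinal transcripts, several of which had at most 1 read in the others. UPK1A stood at 936 ± 804 CPM in Entero, 1070 ± 841 CPM in SIS and 1120 ± 952 CPM in PRS native bladder, UPK2 at 488 ± 379, 501 ± 370 and 445 ± 368 CPM, and DES at 9980 ± 12700, 15100 ± 12300 and 15000 ± 15100 CPM. With the preset correlation 18 of 29 lists were called between SIS and Entero native bladder, 3 between PRS and Entero and 10 between PRS and SIS, and 1, 1 and 0 with an estimated correlation. Smooth muscle genes ranked higher in SIS than in Entero native bladder (adjusted p = 0.00134, adjusted p = 0.482 with an estimated correlation). In edgeR 0 genes passed in the 3 comparisons. Unadjusted p lay under 0.05 for 705 genes (SIS against Entero), 357 (PRS against Entero) and 1196 (PRS against SIS), and DESeq2 called 64, 28 and 114. Without SIS native library 3, 1 gene passed between SIS and Entero.

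Absorptive intestinal genes ranked lower in SIS than in Entero native bladder (adjusted p = 2.17e-36, adjusted p = 0.000172 with an estimated correlation) and lower in PRS than in Entero native bladder (adjusted p = 4.18e-35, adjusted p = 0.000158 with an estimated correlation). Adjusted over the list alone, 14 and 13 of the 28 members were lower, and 0 over all genes tested in edgeR, with 14 and 16 at unadjusted p under 0.05 and 6 and 7 called by DESeq2. SI, the sucrase-isomaltase of the brush border, had 233 reads over the 5 Entero native libraries (1.71 ± 1.38 CPM), 1 over the 5 of the SIS arm (ratio 254, counting interval 45.2 to 10100) and 0 over the 4 of the PRS arm, at least 71.1-fold lower there. FABP2 had 106 reads, 1 read (ratio 116, counting interval 20.3 to 4610) and 0 reads, at least 32.3-fold lower in the PRS arm. VIL1 stood at 0.487 ± 0.186, 0.0645 ± 0.0924 and 0.0195 ± 0.0390 CPM. Secretory and crypt genes did not follow this order in single libraries. OLFM4, of crypt stem cells, stood at 5.83 ± 10.3 CPM in Entero, 5.71 ± 12.1 CPM in SIS and 360 ± 717 CPM in PRS native bladder, with 1440 CPM in PRS library 4. CDX2 had no read in SIS or PRS native bladder, and the source of OLFM4 in those bladders was not tested. SST, somatostatin, is not on the secretory and crypt list. It had no read in Entero native bladder and 48.1 CPM in SIS native library 4, with 0 in the other 4. That library also stood apart in neuronal genes (list mean 3.31), and the source of SST was not tested. B and plasma cell genes ranked lower in SIS than in Entero native bladder (adjusted p = 7.06e-19, adjusted p = 0.13 with an estimated correlation; 11 lower adjusted over the list alone), and higher in PRS than in SIS native bladder (adjusted p = 1.55e-11, adjusted p = 0.497 with an estimated correlation; 13 higher adjusted over the list alone). CD79A stood at 46.3 ± 70.3 CPM in Entero, 1.78 ± 0.94 CPM in SIS and 61.2 ± 92.6 CPM in PRS native bladder, and CR2, a complement receptor of B cells and follicular dendritic cells, at 47.1 ± 81.8, 0.172 ± 0.160 and 52.1 ± 81.1 CPM. The B and plasma cell list mean ran from 1.24 to 6.65 in Entero, -1.05 to 1.27 in SIS and -0.71 to 6.78 in PRS native libraries. These ranges overlapped. FCGBP gave 7.86 (SE 2.25, adjusted p = 0.548) in PRS against SIS native bladder. That test includes the high level of PRS library 4 given under other observations.

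**Figure D2:**
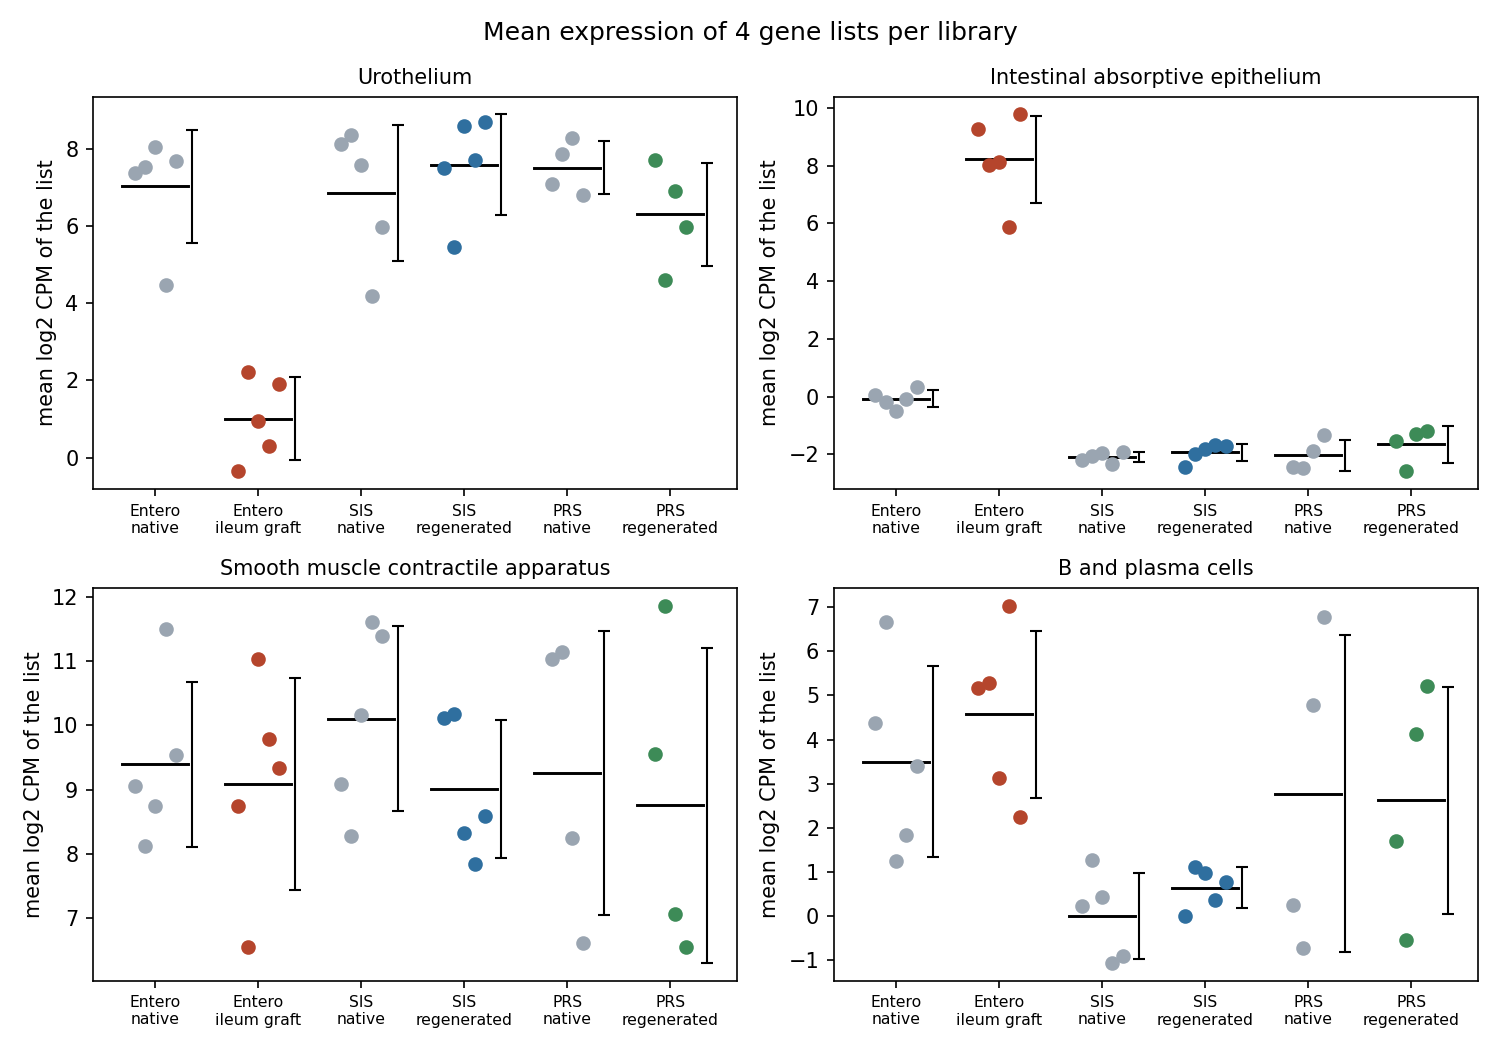
Mean log2 CPM of 4 gene lists (vertical axes) in each library, by group (horizontal axis). Points are libraries, horizontal lines the group means and bars ± 1 SD; urothelial means lie between -0.36 and 2.21 in ileum grafts and between 4.60 and 7.71 in PRS regenerated tissue, and absorptive means between -0.48 and 0.34 in Entero native bladder and between -2.32 and -1.92 in SIS native bladder.

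Over all genes that passed the filter, each ileum graft lay farther from the native bladder of its animal than any regenerated tissue did. The distance (1 minus Pearson's r) was 0.192 ± 0.025 in the Entero arm (n = 5), 0.082 ± 0.057 in the SIS arm (n = 5) and 0.070 ± 0.039 in the PRS arm (n = 4). The Entero arm exceeded the SIS arm by 0.110 and the PRS arm by 0.122, with a two-sided exact permutation p of 0.00794 each, the smallest these designs allow, and 0.0119 adjusted over the 3 comparisons. The SIS and PRS arms differed by 0.012 (exact permutation p = 0.706). For scale, native libraries of different animals lay at a median distance of 0.0733, with a range of 0.0231 to 0.217 over 91 pairs.

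**Figure D3:**
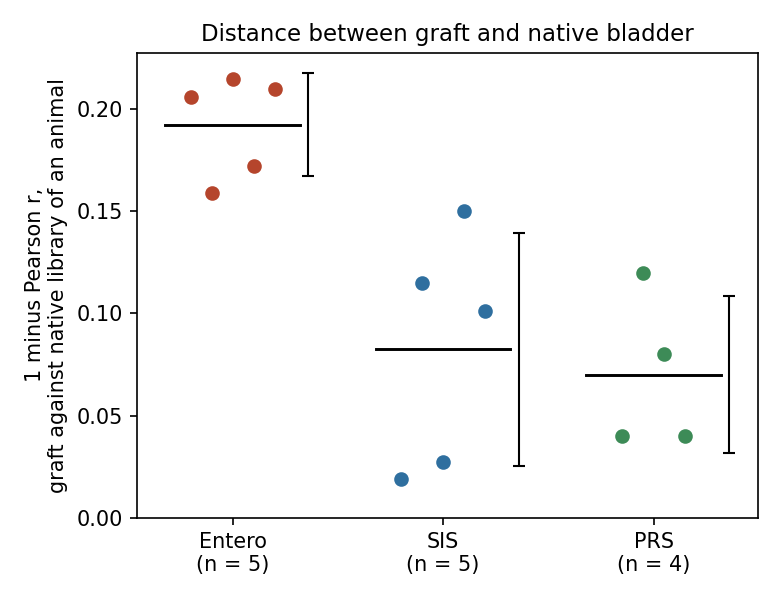
Distance of each graft from the native bladder of its animal, 1 minus Pearson's r of log2(CPM + 1) (vertical axis), by arm (horizontal axis). Points are animals, horizontal lines the means and bars ± 1 SD; the 5 Entero animals lie between 0.159 and 0.215, and the 9 animals of the other arms between 0.019 and 0.150.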

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

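The regroupings of the samples were predicted before their results were seen, first drawn at 60 per comparison and then raised to 100 after those results had been seen. The other tests below, of intestinal transcripts, of the cell-seeded arms and of mitochondrial transcripts, were chosen only after the result was seen.

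Regrouping the 10 libraries of the Entero arm gave as many genes as the real split (2582) in 1 of 100 splits, the real one, and at most 871 in the others, so chance is excluded only among splits drawn without regard to the pairs. Of the 16 splits that part every native library from the graft of its animal, the real one was the highest and the next gave 871, and 16 splits are too few for a share under 0.05. Splits that keep a pair together gave at most 347. Chance can also be excluded for the difference between the SIS and Entero arms (1118 genes, highest other 760), the PRS and Entero arms (606, highest other 290), SIS tissue against ileum (3627, highest other 2207) and PRS tissue against ileum (2392, highest other 1379), each with 1 of 100 splits. The comparisons with 0 calls cannot exclude it. Any split calls at least 0 genes, so that all 100 splits gave as many was fixed in advance. They were SIS tissue against native bladder (highest other 2), the difference between the PRS and SIS arms (0), PRS against SIS tissue (9), and native bladders of SIS and Entero (0), PRS and Entero (3) and PRS and SIS (1). For those counts of 0 in edgeR, the counts at unadjusted p under 0.05 were 831, 677, 763, 705, 357 and 1196, and DESeq2 called 70, 20, 15, 64, 28 and 114. In the PRS arm, where edgeR called 0 genes (613 at unadjusted p under 0.05, 26 in DESeq2), all 35 splits likewise gave as many by necessity. The highest, with 648 genes, set both libraries of animals 1 and 2 against both libraries of animals 3 and 4. It follows the letter of the animal code and points to a structure of the samples, and the 8 splits that part every pair gave 0.

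The native libraries of the Entero arm held intestinal transcripts. Over 20 genes with at least 20 CPM in ileum and at most 3 reads in the 18 libraries of the cell-seeded arms, their level was 0.023% to 0.184% of the ileum mean. Deeper sequencing is argued against, as the median total of these libraries was 0.86 times that of the other native libraries. Across the 20 genes the median rank correlation of a native library with mean ileum was 0.57, consistent with RNA or reads of ileum in these libraries, and genes are not independent replicates. Whether the source is the graft of the same animal stays open (mean correlation 0.64 with the own graft and 0.46 with others, exact one-sided permutation p = 0.0833, smallest possible 0.00833), and whether it arose in the bladder, at sampling or in library preparation was not tested.

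No gene was called by edgeR between regenerated and native tissue in the SIS or the PRS arm (831 and 613 at unadjusted p under 0.05, 70 and 26 in DESeq2). With the smooth muscle score of each library as a covariate, which 4666 of 16487 genes followed, edgeR called 0 genes in both arms, which at this power does not decide whether the share of muscle in each piece hides changes. Too few animals may be part of it, as 45.5% of genes changed 4-fold were called in counts simulated for the SIS arm, and 27.8% for the PRS arm. The bound of 50% used for that reading was set after the 45.5% had been seen. That the regenerated tissue resembles native bladder stays open, as a count of 0 does not show it.

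The mitochondrial share was higher in ileum grafts than in native bladder of the same arm by 11.4 percentage points. A single library as its source is argued against, since the lowest ileum share lay 3.5 points above the highest native share, and an effect on the scaling of all other genes is argued against, since 2529 of the 2582 calls stayed without the mitochondrial genes. Of 47 tested nuclear genes of the respiratory chain, 20 rose and 0 fell, and their median log2 fold change of 0.86 lay at percentile 100 of 10000 random lists matched on expression (95th percentile 0.18). The random lists do not carry the correlation among respiratory chain genes, and genes are not replicates, so the percentile is no test over animals. More mitochondria in the grafted tissue is a candidate explanation. The list of 53 genes was trimmed from a longer one whose median had been seen, and tissue quality was not tested.

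Single libraries far from the others of their group were sought in 189 groups of values, where chance gives about 9 at 1 in 20, and 21 were found, 20 of them among 174 groups of list means (mean log2 CPM). The mitochondrial share was 33.9% in Entero ileum 1 (others 14% to 18.5%). Among native libraries of the Entero arm, library 4 stood apart in urothelium (4.46, others 7.37 to 8.04), squamous genes (-0.34, others 2.57 to 3.65) and adipocytes (6.77, others 1.55 to 2.79), and library 2 in interferon response (6.02, others 3.73 to 4.37). Among ileum grafts, library 3 stood apart in elastic fibre genes (7.19, others 6.11 to 6.38) and library 4 in hypoxia genes (5.56, others 5.82 to 5.9). Among SIS native libraries, library 4 stood apart in neurons (3.31, others -0.29 to 0.1) and interferon response (3.13, others 3.83 to 4.04), and library 1 in adipocytes (4.89, others 2.69 to 3.23). Among SIS regenerated libraries, library 2 stood apart in fibrillar collagen (9.22, others 6.33 to 6.91), interstitial cells (4.45, others 2.92 to 3.24) and mesenchymal stromal cells (6.56, others 5.35 to 5.66), and library 3 in cell division (2.37, others 1.44 to 1.5). Among PRS native libraries, library 4 stood apart in endothelium (4.18, others 3.77 to 3.8) and adipocytes (5.17, others 1.54 to 2.13), and library 3 in hypoxia genes (4.45, others 5.46 to 5.58). Among PRS regenerated libraries, library 1 stood apart in neurons (0.19, others -0.88 to -0.76), and library 2 in mesenchymal stromal cells (6.42, others 5.32 to 5.37), inflammatory genes (0.44, others 2.66 to 2.98) and red blood cells (4.13, others 0.49 to 0.74).

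Differences of the graft-minus-native change between arms, tested as such, were found for 1118 genes between SIS and Entero and for 606 between PRS and Entero. Among the genes named for SIS against Entero, the difference of log2 fold change was 8.2 for UPK1A, 8.45 for UPK2, 8.04 for UPK3A, 10.6 for TP63, 9.68 for WNT7B, 9.98 for SHH, 4.17 for IL33, 4.21 for GATA2 and 5.19 for TRPV4. It was -11.2 for SLC6A19, -9.73 for VIL1 and -4.38 for CA9. CXCL8 (8.19) and PTGS2 (5.18) lost their calls without SIS regenerated library 2 (5.08 and 2.32). For PRS against Entero it was 6.39 for UPK1A, 7.52 for UPK3A, 8.49 for TP63, 8.56 for WNT7B, 8.53 for SHH, 4.24 for IL33, 4.01 for LEPR, -8.69 for ANPEP and -9.01 for MTTP. The UPK1A call of that comparison was lost without Entero native library 3 (5.76), PRS native libraries 1 (6.16) and 4 (6.03) or PRS regenerated library 1 (5.18). With the animal as a block the calls of UPK1A and UPK3A for PRS against Entero were lost too, as was that of PTGS2 for SIS against Entero.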

How the results depend on the processing

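The fits without mitochondrial genes, with the smooth muscle score and of the cell-seeded arms alone were tests chosen after the result was seen, and they moved no count of genes by more than 1.5 times. With the animal as a block, the differences of change fell to 678 genes (SIS against Entero) and 240 (PRS against Entero), and no other count moved by more than 1.5 times. DESeq2 called 70 genes in the SIS arm and 26 in the PRS arm, 1744, 1176 and 20 for the differences SIS against Entero, PRS against Entero and PRS against SIS, 15 between PRS and SIS tissue, and 64, 28 and 114 between native bladders of SIS and Entero, PRS and Entero, and PRS and SIS. In a single draw of counts simulated from edgeR's estimates of spread, 29 of 98 DESeq2 calls for the SIS arm and 31 of 103 for the PRS arm were false. Those shares need not hold for the real calls. With the compared groups alone, 371 genes differed in change between PRS and Entero, and 2314 and 1033 differed between SIS or PRS tissue and ileum. Across arms the samples share only a number, and taking it as a block gave 1503 and 263 genes for these graft comparisons and 16 between SIS and Entero native bladder, and ended 9 of the 11 calls named for PRS tissue against ileum. The letter of the animal code as a covariate gave 2073, 1006 and 3. The cause was not tested for any of these.

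Leaving out each library in turn gave 390 to 743 genes for the difference PRS against Entero (lowest without PRS regenerated library 1), 0 to 3 in the PRS arm (3 without native library 4) and 0 to 1 between SIS and Entero native bladder (1 without SIS native library 3), and moved no other count by more than 1.5 times. Distances kept their direction and side of the threshold between the Entero arm and the others. Of 188 tests of named genes 93 were called; 78 kept the call in all alternatives, 15 lost it in some and 0 reversed. Of those not called 21 gained a call in some alternative, and 106 of their values changed sign. Of 109 list calls, 102 were lost with an estimated correlation, and fry lost 76 and added 11. With the animal as a block, which applied to 174 list tests, 2 calls were lost and 7 added. With the median-of-ratios factors the median of all genes moved by at most 0.07 (log2). Depth limits the genes at 0: 3 counts over the ileum libraries correspond to 0.0237 CPM.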

Other observations

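The genes and libraries below were singled out after their values were seen, and the differences between single libraries were not tested. Some regenerated PRS libraries held high levels of secreted mucosal proteins. BPIFB1, of mucosal glands, was at 3770 and 3840 CPM in PRS regenerated libraries 3 and 4, 521 CPM in PRS native library 4, 286 CPM in SIS regenerated library 4, 15.5 CPM in PRS regenerated library 1 and 0 in library 2. FCGBP, a mucus protein, was at 42000 and 27800 CPM in PRS regenerated libraries 3 and 4, and at 11600 CPM in PRS native library 4. LCN2, an antibacterial protein, was at 4970 and 7380 CPM in these 2 regenerated libraries and at 2420 CPM in that native one, and PIGR, which carries immunoglobulin across epithelium, at 6730, 7000 and 4270 CPM. In PRS regenerated libraries 1 to 4, UPK2 stood at 444, 42.1, 68.2 and 10.1 CPM and UPK3A at 854, 97.6, 1140 and 1140 CPM.

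Genes of B cell follicles were high in single libraries. MS4A1, a B cell surface protein, was at 30 and 147 CPM in PRS native libraries 3 and 4 and at 0 in libraries 1 and 2, at 143 CPM in Entero native library 2 and at 164 CPM in Entero ileum 4. CXCL13, which attracts B cells, was at 450 CPM in Entero native library 2, 458 CPM in PRS native library 4 and 331 CPM in Entero ileum 4.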
